A study of Mus musculus with 36 samples.

How the data were processed

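The series holds 36 samples of mouse embryonic fibroblasts, connective tissue cells grown from mouse embryos, of the strain C57BL/6J. Cells were left in normal medium or stressed by adding sorbitol, a sugar alcohol that raises the osmolarity of the medium. The 9 conditions were unstressed cells, 500 mOsm for 2 h, 600 mOsm for 2 h, 700 mOsm for 15 min, 700 mOsm for 2 h, and 15 min or 2 h of recovery after each of the 700 mOsm exposures. Each condition had 2 ribosome footprint (Ribo-seq) and 2 cytoplasmic RNA-seq libraries. Per the labels' protocols, footprints came from the pooled gradient fractions from the single ribosome peak downward, digested with RNase I, and fragments of 28 to 30 nt were cut from a gel. Cycloheximide, which stops ribosomes on the mRNA, was in the lysis buffer.

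The authors deposited 1 list per library with a transcript identifier and a value. The file names give RPKM (reads scaled by length and by library total) for the footprint libraries and FPKM (the same for fragments) for the RNA libraries, and the deposited values had the steps that these units give. The tools cutadapt, Bowtie and STAR and the mouse build GRCm38 are named, per the submitters' processing notes, without versions or roles. The annotation and the way reads were counted are not given in the sources used here. The deposited lists name transcripts by Ensembl transcript identifier and do not pair them with gene names, and the name tables used here do not hold these identifiers. No transcript was therefore given a gene name, the gene lists and named genes that had been fixed before the data were examined were not applied, and at most 2 identifiers that rose and 2 that fell are printed.

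The deposited RPKM and FPKM values were whole reads divided by a length and by a total. Both were solved for: the total from the greatest common divisors of the inverse values within a library, and each transcript's length from the denominators over the 18 libraries of an assay. The resulting read numbers were whole within a relative tolerance of 1e-09 for 100.0% of the values in every library. This follows largely by construction, since the lengths were taken from the same values, and is no separate check. On simulated footprint values, the read number was recovered exactly for at least 99.74% of the transcripts listed in each library. The lengths behind the footprint values were multiples of 3 and are called coding length here, with a median of 466 codons. Those behind the RNA values had a median of 2648 nt. Of the 11028 transcripts in both assays, 99.9% had a coding length within the transcript length. Footprint libraries held 734083 to 9124787 reads on listed transcripts and RNA libraries 6851958 to 55262396. RNA lists started at 1 read. In the footprint lists at most 0.304% of the listed transcripts of a library had fewer than 5 reads, so that an unlisted transcript had too few reads for listing and was not necessarily at 0. Unlisted transcripts were set to 0. Read numbers limit precision through counting error only, since reads without molecular identifiers are not independent molecules.

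The 2 libraries of each condition were compared by a chi-square statistic of their reads per transcript, over transcripts with at least 40 reads in the pair. In the 9 footprint pairs the mean statistic per degree of freedom was 1.005 to 1.085, where sampling noise alone gives 1, and in the 9 RNA pairs it was 3.444 to 47.079. The 2 footprint libraries of a condition thus differed by little more than sampling noise. They were averaged and counted as 1 sample, so that a footprint comparison sets 1 sample against 1 and has no replicate check, no SD and no p-value. The limma tests planned for footprints and translational efficiency were not used as results and, after that check, stand only as an alternative. The RNA-seq groups were kept as n = 2. The labels do not say whether these were separate cultures, so p-values measure the spread between these libraries, which may be technical.

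Each library was divided by its median ratio to the transcript-wise geometric mean over transcripts above 0 in all 18 libraries of the assay with a mean of at least 10 (4619 transcripts for footprints, 5705 for RNA). A change is therefore relative to the typical abundant transcript, and no change in the total amount of translation can be read from it. Changes are differences of log2(scaled value + 1), which understates changes of low transcripts. Transcripts with a mean scaled value of at least 2 over the 18 libraries were kept, which left 8849 for footprints, 9275 for RNA and 8446 for both. RNA was tested with limma 3.58.1 in R 4.3.3: 1 fit over all 18 RNA libraries with 9 group means, a precision weight per group, a mean-variance trend, two-sided tests, and Benjamini-Hochberg adjustment at 0.05. "Rose" and "fell" are used of RNA past that threshold. Footprints and translational efficiency (the footprint change minus the RNA change, on the log2 scale) were summarised as the number of transcripts at least 2-fold higher or lower. Classes of transcripts by coding length and by non-coding length (transcript minus coding length) were chosen after seeing the data, in a search that also looked at classes of abundance and of translational efficiency in unstressed cells, which are not reported. Coding length was divided at 100, 200, 400, 800 and 1600 codons and non-coding length at 500, 1000 and 2000 nt, each class leaving out its lower bound. The median footprint change of a class was placed among those of 10000 random lists of the same size matched on mean footprint level, as a description of these libraries. The lists were not matched on coding length or reads, and at 1 level a shorter coding sequence has fewer reads. Other steps used Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and Matplotlib 3.10.9.

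Both kinds of summary were tested on simulated data. All simulated RNA libraries had 1 depth, a median over the 18 libraries, and 1 spread per group, taken from the real pairs, was used for all transcripts. With 200 of 9275 transcripts changed, the RNA fit recovered 100% of the 2-fold and 100% of the 4-fold changes in each of the 8 comparisons with unstressed cells. False calls made up 2% to 5.7% of all calls, and were above 5% at 500 mOsm (5.7%) and at 600 mOsm (5.2%). The real depths ran from 6851958 to 55262396 reads, so these rates need not hold for the real libraries. Footprint reads drawn with 200 of 9213 transcripts changed 4-fold gave 98.5% of these past 2-fold at the depth of the 700 mOsm 2 h libraries, together with 958 unchanged transcripts past 2-fold from counting noise and the listing minimum alone. At the depth of the 700 mOsm 15 min libraries there were 808 such unchanged transcripts, and at that of the 600 mOsm libraries 136.

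The alternatives listed before the data were examined were the values as deposited without further scaling, a pseudocount of 0.25, no filter on low values, the replicate number as a block, equal weights, a fit on the compared groups only, each library left out in turn, and, for 2 RNA groups, exchanged groups. In those 2 groups, recovery for 2 h after 15 min at 700 mOsm and recovery for 15 min after 2 h at 700 mOsm, the names of the RNA files read the other way round from the labels. The labels were used throughout, and these libraries are called "the libraries labelled" with their group. The planned limma test, counting each deposited footprint library as a replicate, became an alternative after seeing the data, without and with the replicate number as a block. Added then were a set of 2784 transcripts with at least 100 reads expected in the shallowest pair of footprint libraries at their mean share over the 18 libraries, the same set from the share in the unstressed libraries (3068 transcripts, tried first), limma-voom on the recovered RNA reads, and a fit without the 2 RNA groups in doubt. A block that joined the footprint and RNA libraries by replicate number was tried for 2 comparisons and dropped, since nothing shows that these numbers pair samples. The rule for named transcripts took those with the largest change among those past the threshold whose 2 treated libraries lay on the same side of both control libraries and whose mean scaled value was at least 10 in 1 of the 2 groups. For footprints, which have no threshold, it was applied to size alone.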

Results

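Ribosome footprints and cytoplasmic RNA were measured in mouse embryonic fibroblasts before, during and after hyperosmotic stress, to ask how translation responds to the strength and length of the stress and to its removal. Footprints, the stretches of mRNA covered by ribosomes, were reported as RPKM over the coding sequence, and RNA as FPKM over the transcript. The 2 footprint libraries of each condition differed by little more than sampling noise and were counted as 1 sample, so footprint values have no replicate error. RNA values have n = 2 per condition.

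The footprint libraries covered fewer transcripts as the stress became stronger. Unstressed cells had 7261234 and 7593983 footprint reads on 10421 and 10458 listed transcripts. At 500 mOsm for 2 h there were 4306252 and 4326915 reads on 9847 and 9852 transcripts, and at 600 mOsm for 2 h 2702679 and 2283553 reads on 9044 and 8765. At 700 mOsm the libraries were the shallowest, with 823957 and 1070017 reads on 6193 and 6716 transcripts after 15 min, and 734083 and 909760 reads on 6624 and 7145 after 2 h. Thinned to 734083 reads and counted from 5 reads up, the unstressed libraries covered 8306 and 8331 transcripts, those at 700 mOsm for 15 min 5982 and 6040, and those at 700 mOsm for 2 h 6624 and 6704. In the recovery conditions 9616 to 10513 transcripts were listed, from 2372665 to 9124787 reads. The 10 highest transcripts took 7.78% and 7.81% of the summed footprint values in unstressed cells, 13.5% in both libraries at 700 mOsm for 15 min, and 14.9% in both at 700 mOsm for 2 h. RNA libraries held 6851958 to 55262396 reads. The shallowest was replicate 2 of 700 mOsm for 2 h and the deepest replicate 1 of the unstressed cells.

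Footprint values moved further from those of unstressed cells with each step in osmolarity at 2 h. Of 8849 transcripts, 66 were at least 2-fold higher and 1484 at least 2-fold lower at 500 mOsm, 331 and 3132 at 600 mOsm, and 1435 and 4230 at 700 mOsm. The SD of the log2 change across transcripts was 0.74, 1.28 and 1.81. After only 15 min at 700 mOsm, 1487 transcripts were at least 2-fold higher and 4323 lower, with an SD of 2.02. The 2 libraries of a condition differed at least 2-fold from each other in 17 transcripts for unstressed cells, 91 at 500 mOsm, 388 at 600 mOsm, 1125 at 700 mOsm for 15 min and 1254 at 700 mOsm for 2 h. The split depended on the scaling: the footprint values as deposited gave 513 higher and 2984 lower at 600 mOsm, and at 700 mOsm 744 higher and 5095 lower after 15 min and 903 higher and 5047 lower after 2 h, because scaling to the typical abundant transcript moved the libraries by -0.12 at 600 mOsm and by 0.56 and 0.47 at 700 mOsm on the log2 scale. Counting noise and the listing minimum alone took 808 of 9213 simulated transcripts past 2-fold at the depth of the 15 min libraries and 958 at that of the 2 h libraries. Among the 2784 transcripts with at least 100 expected reads, 814 were higher and 794 lower after 15 min, and 682 higher and 891 lower after 2 h. With that set drawn from the unstressed libraries alone, 708 of 3068 were higher and 1120 lower after 15 min, and 559 higher and 1268 lower after 2 h.

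**Figure D1:**
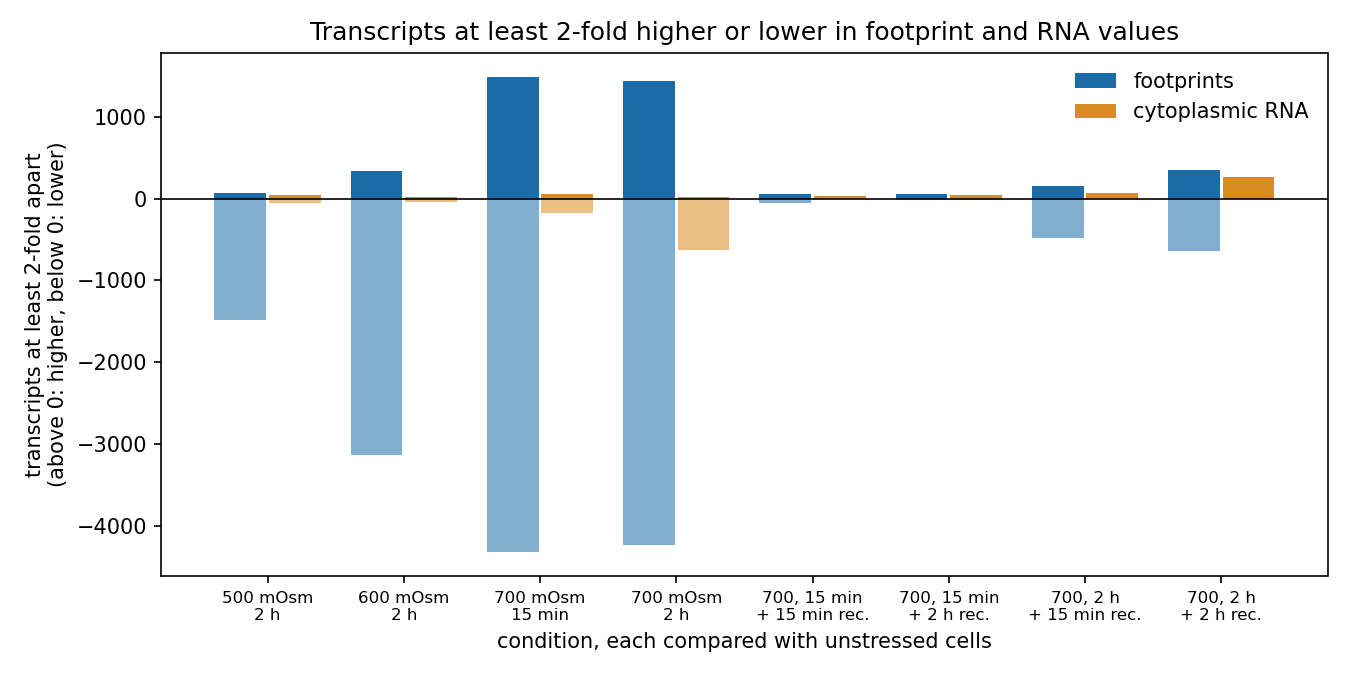
Number of transcripts at least 2-fold higher (above 0) or lower (below 0, paler) than in unstressed cells in each condition, for footprints (blue, 1 sample per condition) and cytoplasmic RNA (orange, mean of 2 libraries). Footprints at 700 mOsm show 4323 lower transcripts after 15 min and 4230 after 2 h, while the tallest RNA bar is 634 lower transcripts at 700 mOsm for 2 h.

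The footprint change followed coding length, and differently at the 2 times of the strongest stress. After 15 min at 700 mOsm, the 373 transcripts with over 1600 codons had a median log2 change of 1.67, with quartiles of 1.20 and 2.15, and 319 of them were at least 2-fold higher against 2 lower. The 3166 transcripts with over 400 and up to 800 codons had a median of -1.72, with 222 higher and 1975 lower. At 2 h of the same osmolarity the longest class was at -0.65, with 21 higher and 124 lower, and the class of 400 to 800 codons at -1.13. Among transcripts with at least 100 expected reads the class of 400 to 800 codons was at -0.69 after 15 min and -0.48 after 2 h, and the longest class at 2.09 and -0.85, so the order of the 2 classes at 2 h turned. With that set drawn from the unstressed libraries the values were -1.17 and -0.91 against 2.00 and -0.93. Random lists matched on footprint level spanned -2.0 to -1.32 for the longest class after 15 min and -1.69 to -1.19 after 2 h (95% range), so the class lay above all 10000 of them at both times. These lists were not matched on reads. At 1 level a shorter coding sequence has fewer reads and more often goes unlisted, which lowers the lists. At 2 h, where the order of the classes turned among well-read transcripts, the place among the lists therefore decides nothing. The medians of the 2 libraries for the longest class were 1.72 and 1.66 after 15 min and -0.62 and -0.64 after 2 h. On the values as deposited the longest class stood at 1.16 after 15 min and -1.05 after 2 h.

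Short coding sequences past the filter on low values had a median footprint change above 0 at 600 and 700 mOsm. The 180 transcripts with up to 100 codons had a median footprint change of 0.09 at 500 mOsm, within the 95% range of matched random lists (-0.02 to 0.11), and of 0.40 at 600 mOsm and 0.99 at 700 mOsm for 2 h. At 600 mOsm 19 were at least 2-fold higher and 27 lower, against the direction of the median, and at 700 mOsm for 2 h 89 and 51. Without the filter on low values the median at 600 mOsm was 0.19. At 600 mOsm the medians went down with coding length, from -0.27 at 200 to 400 codons (-0.16 as deposited) and -0.50 at 400 to 800 to -0.98 at 800 to 1600 and -1.03 over 1600 codons. Random lists matched on footprint level went down in the same order, with 95% ranges of -0.37 to -0.27, -0.58 to -0.48, -0.76 to -0.59 and -1.01 to -0.62, so that only the 2 longest classes lay below theirs. Among transcripts with at least 100 expected reads the 4 medians were 0.05, -0.09, -0.47 and -0.79. The first was -0.18 with that set drawn from the unstressed libraries, so its sign depended on the set. Without the filter on low values the longest class was at -0.65, above that of 800 to 1600 codons at -0.75. At 700 mOsm for 15 min the class of up to 100 codons was at 0.65, which was 0.07 on the values as deposited and 0.00 without the filter on low values. At 700 mOsm for 2 h it was 0.50 as deposited and 0.03 without the filter. Among transcripts with at least 100 expected reads it was 0.61 at 600 mOsm, and 1.22 and 1.69 at 700 mOsm for 15 min and 2 h. Non-coding length went with lower footprint values as well. At 700 mOsm for 2 h, 1983 transcripts with up to 500 nt of non-coding sequence had a median change of -0.12, and 2433 transcripts with over 2000 nt one of -1.45. Matched random lists differed in the same direction by less, with 95% ranges of -0.70 to -0.53 and -1.17 to -1.01. Among transcripts with at least 100 expected reads the 2 medians were 0.51 and -0.66, or 0.24 and -1.19 with that set drawn from the unstressed libraries. The first was -0.57 on the values as deposited and -0.24 without the filter on low values.

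**Figure D2:**
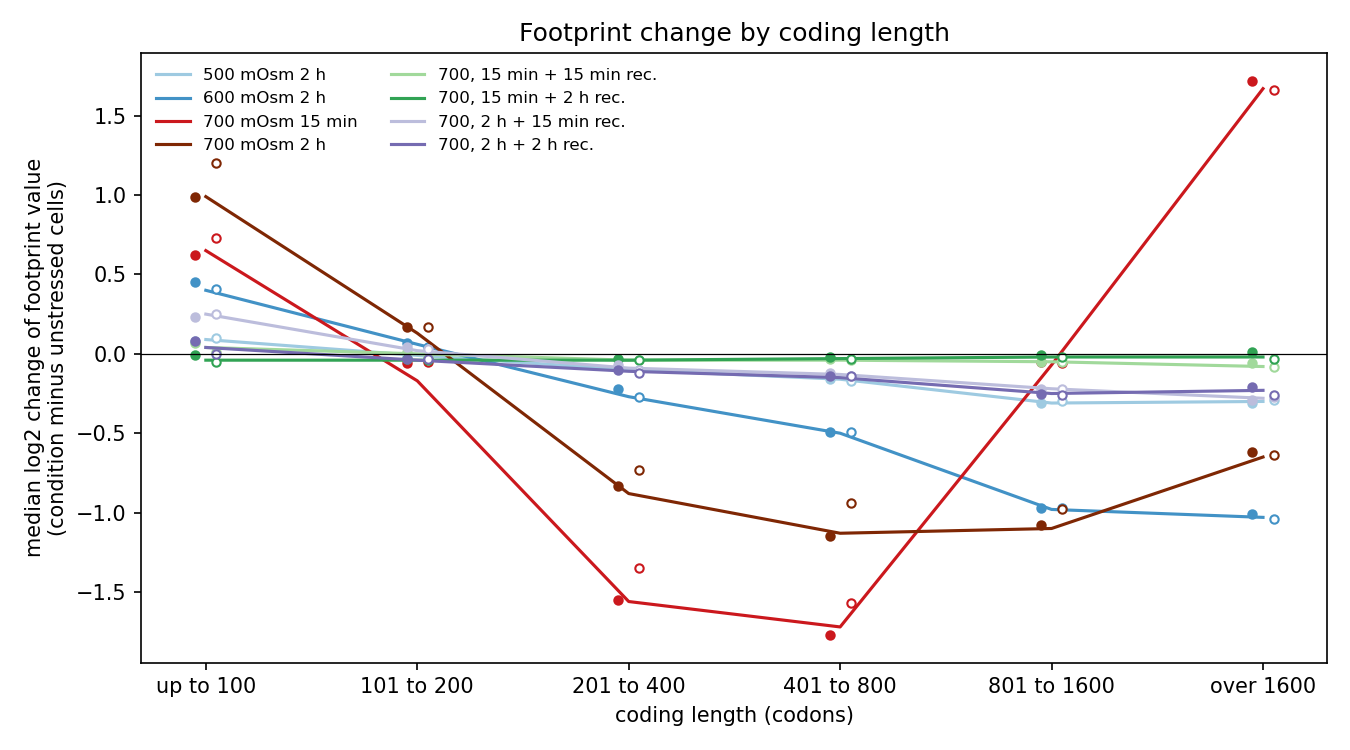
Median log2 change of the footprint value against unstressed cells by coding length in codons, 1 line per condition; filled and open points are the medians of replicate 1 and replicate 2 libraries. The line of 700 mOsm for 15 min falls to -1.72 at over 400 and up to 800 codons and rises to 1.67 over 1600 codons, and the 4 recovery lines stay between -0.28 and 0.25.

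Between 600 and 700 mOsm at 2 h, 1327 transcripts had at least 2-fold higher and 2025 at least 2-fold lower footprint values at the higher osmolarity. On the values as deposited the split was 542 higher and 3203 lower. The 2 conditions also differed in depth, with 2283553 and 2702679 reads at 600 mOsm against 734083 and 909760 at 700 mOsm.

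Footprint values came back towards those of unstressed cells within 15 min of return to normal medium. From 15 min of stress at 700 mOsm to 15 min of recovery, 4271 transcripts had at least 2-fold higher and 1514 at least 2-fold lower footprint values (5077 and 717 as deposited). From 2 h of stress to 15 min of recovery the numbers were 3746 and 1212 (4741 and 564 as deposited). Compared with unstressed cells, recovery from 15 min of stress left 57 transcripts higher and 56 lower after 15 min, and 61 higher and 24 lower after 2 h. Without the filter on low values these were 62 and 154, and 83 and 42, and with a pseudocount of 0.25 they were 77 and 101, and 77 and 39. The 2 libraries of these recovery conditions differed at least 2-fold from each other in 60 and 12 transcripts. Recovery from 2 h of stress left 158 higher and 488 lower after 15 min, and 344 higher and 638 lower after 2 h. Set directly against each other, 2 h of recovery after the long stress had 342 transcripts at least 2-fold higher and 553 lower than 2 h of recovery after the short stress. After 15 min of recovery from the long stress, transcripts with up to 100 codons had a median footprint change of 0.25, or 0.01 without the filter on low values, and those with over 1600 codons one of -0.28. The 2433 transcripts with over 2000 nt of non-coding sequence had a median of -0.30, below all 10000 matched random lists.

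RNA changed in many transcripts at 700 mOsm, though by smaller factors than footprints. At 700 mOsm for 15 min 1791 of 9275 transcripts rose and 2826 fell, and at 700 mOsm for 2 h 1730 rose and 2876 fell (limma, adjusted p under 0.05). At least 2-fold differences were fewer, with 53 higher and 179 lower after 15 min and 23 higher and 634 lower after 2 h. RNA of transcripts with few codons was on the rising side: of 173 tested transcripts with up to 100 codons, 114 rose and 9 fell after 15 min, and 89 rose and 13 fell after 2 h. Of 348 with over 1600 codons, 50 rose and 159 fell after 15 min, and 36 rose and 229 fell after 2 h, with median log2 changes of -0.24 and -0.61. Non-coding length showed the same order: of 2283 transcripts with over 2000 nt, 125 rose and 1351 fell after 2 h, and of 1909 with up to 500 nt, 754 rose and 205 fell. On the FPKM values as deposited the split after 2 h was 1243 risen and 3285 fallen, and without replicate 1 of the unstressed cells 1127 rose after 2 h. The largest fall by the fixed rule after 2 h was that of ENSMUST00000060366, with a coding length of 485 codons, from 71.8 ± 0.334 to 11.5 ± 1.56 scaled FPKM (mean ± SD, n = 2 each; log2 change -2.54, SE 0.097, limma adjusted p = 9.63e-11).

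At 500 mOsm for 2 h 144 transcripts rose and 175 fell in RNA, and at 600 mOsm for 2 h 359 rose and 845 fell (limma, adjusted p under 0.05). The SD of the RNA change across all 9275 transcripts was 0.25 and 0.28 on the log2 scale, against 0.44 and 0.52 at 700 mOsm for 15 min and 2 h. At 500 mOsm the direction of the split turned without the filter on low values, with 252 risen and 217 fallen, and without replicate 2 of the unstressed cells, with 143 and 120. Without replicate 1 of the unstressed cells 64 rose and 85 fell at 500 mOsm and 81 and 269 at 600 mOsm, without replicate 2 of 500 mOsm 94 and 104, and without replicate 2 of the unstressed cells 508 fell at 600 mOsm. Equal weights gave 423 risen and 513 fallen at 500 mOsm and 880 and 1405 at 600 mOsm, voom on recovered reads 750 and 884, and 1344 and 1818, and a fit on the compared groups only 234 risen at 600 mOsm. The 2 unstressed RNA libraries had a mean chi-square per degree of freedom of 47.079, against 3.444 to 22.971 in the other conditions. Any difference beyond sampling noise raises that statistic more in deeper libraries, and theirs had 55262396 and 39748466 reads. It therefore cannot rank the pairs by spread. The fit gave the unstressed group the lowest weight, 0.32 against 0.54 to 2.226 for the other groups.

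RNA during recovery had more risen than fallen transcripts in 3 of the 4 groups as labelled. After 15 min of recovery from the short stress 407 rose and 240 fell. After 2 h of recovery from the long stress 1286 rose and 768 fell, and of the 259 transcripts with at least 2-fold differences 257 were higher. The largest rise by the fixed rule was that of ENSMUST00000027941, with a coding length of 182 codons, from 1.55 ± 0.366 to 143 ± 3.02 scaled FPKM (mean ± SD, n = 2 each; log2 change 5.83, SE 0.181, limma adjusted p = 8.92e-13). In the libraries labelled 2 h of recovery after 15 min of stress 456 rose and 776 fell, and in those labelled 15 min of recovery after 2 h of stress 750 rose and 582 fell, or 632 and 780 on the values as deposited. Without the filter on low values 599 rose and 468 fell after 15 min of recovery from the short stress, and 2279 and 608 after 2 h of recovery from the long stress. Without replicate 1 of the unstressed cells 213 rose and 106 fell after 15 min of recovery from the short stress, 122 and 151 in the group labelled 2 h of recovery after the short stress, and 520 and 90 after 2 h of recovery from the long stress. Without replicate 2 of the unstressed cells 147 rose and 55 fell after 15 min of recovery from the short stress, 465 fell in the group labelled 2 h of recovery after the short stress, and 173 rose and 84 fell in that labelled 15 min of recovery after the long stress. Leaving out replicate 2 of the treated group gave 194 and 429 for the group labelled 2 h of recovery after the short stress and 456 and 295 for that labelled 15 min of recovery after the long stress. For 15 min and 2 h after the short stress and 15 min and 2 h after the long stress, as labelled, equal weights gave 748 and 667, 1159 and 1743, 1379 and 1468 (the direction turned), and 1818 and 1272. Voom on recovered reads gave 1043 and 1030, 1464 and 2111, 1280 and 1163, and 2242 and 1740, and fits on the compared groups only 239 and 83, 161 and 341, 571 and 306, and 1197 and 439.

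Footprint values went less with RNA values during stress than before it, and translational efficiency, the footprint value relative to the RNA value, spread out. Across 8446 transcripts Spearman's rho of footprint and RNA levels was 0.82 in unstressed cells, 0.68 at 500 mOsm, 0.61 at 600 mOsm, 0.65 at 700 mOsm for 15 min and 0.67 at 700 mOsm for 2 h, and 0.74 to 0.82 in recovery; these are correlations across transcripts, which are not independent replicates. The SD of the log2 ratio went from 1.07 in unstressed cells to 1.52, 1.87, 2.19 and 2.09 in the same order of stresses. Low depth and the listing minimum may widen it. The SD of the log2 difference between the 2 footprint libraries of a condition was 0.18 in unstressed cells. At 700 mOsm it was 1.12 after 15 min and 1.18 after 2 h. The ratio was not examined in well-read transcripts alone. Translational efficiency was at least 2-fold higher in 29 and lower in 1431 transcripts at 500 mOsm, 210 and 2985 at 600 mOsm, 1236 and 3992 at 700 mOsm for 15 min, and 1197 and 3567 at 700 mOsm for 2 h. On the values as deposited the split was 393 and 2803 at 600 mOsm, and the 700 mOsm splits were 609 and 4679 after 15 min and 707 and 4253 after 2 h. Without the filter on low values 52 were higher and 1766 lower at 500 mOsm. After recovery from the long stress for 2 h, 52 transcripts were higher and 648 lower, or 127 and 916 without the filter. After 15 min of recovery from the short stress, 31 were higher and 44 lower, or 44 and 176 without the filter and 39 and 71 with a pseudocount of 0.25.

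Footprint values were set beside the RNA calls to ask whether both moved together. At 600 mOsm for 2 h, 73.5% of the 800 transcripts with fallen RNA had at least 2-fold lower footprint values and 0.1% at least 2-fold higher ones. Of the 341 with risen RNA 7.6% had at least 2-fold higher and 26.1% at least 2-fold lower values, and of the 7305 with no RNA call 3.3% and 32.7%. At 700 mOsm for 2 h, 35.8% of the 1650 transcripts with risen RNA had at least 2-fold higher and 23.2% at least 2-fold lower footprint values, against 2.3% and 68.4% of the 2672 with fallen RNA and 16.5% and 44.3% of the 4124 with no RNA call. At 2 h of recovery from the long stress, 250 of the 1163 transcripts with risen RNA had at least 2-fold higher and 21 at least 2-fold lower footprint values. Across 8446 transcripts Pearson's r of footprint and RNA changes was 0.22 at 500 mOsm, 0.31 at 600 mOsm, 0.41 and 0.39 at 700 mOsm for 15 min and 2 h, 0.35 for 15 min of recovery after the short stress and 0.62 for 2 h of recovery after the long stress. Spearman's rho of the same changes was 0.12, 0.31, 0.43, 0.41, 0.32 and 0.39 in the same order. For the libraries labelled 2 h of recovery after the short stress Pearson's r was -0.16 and for those labelled 15 min of recovery after the long stress -0.07. With these 2 RNA groups exchanged it was 0.58 and 0.45. The translational efficiency of these 2 groups depended on the same choice. As labelled, 123 transcripts were higher and 60 lower after 2 h of recovery from the short stress, and 234 and 616 after 15 min of recovery from the long stress. Without RNA replicate 2 of the unstressed cells, 93 were lower after 2 h of recovery from the short stress. Without the filter on low values the numbers were 162 and 102, and 294 and 960, and with a pseudocount of 0.25 97 were lower after 2 h of recovery from the short stress. Exchanged, the numbers were 5 and 22, and 101 and 268.

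**Figure D3:**
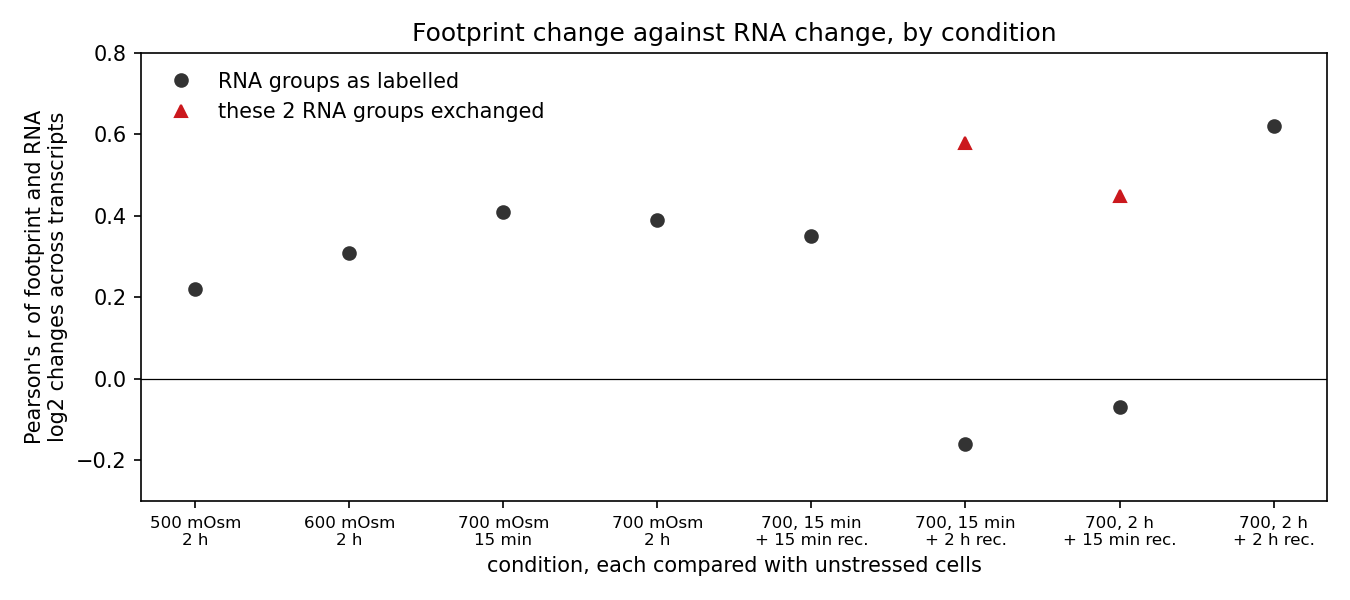
Pearson's r across 8446 transcripts between the log2 change of footprints and that of RNA, each against unstressed cells, by condition; circles use the RNA groups as labelled and triangles the 2 groups exchanged. As labelled, 2 h of recovery after 15 min of stress stands at -0.16 and 15 min of recovery after 2 h of stress at -0.07, and exchanged at 0.58 and 0.45.

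Some transcripts were in the footprint lists of 1 condition and not of the other. By the fixed rule applied to size, ENSMUST00000184858, with a coding length of 723 codons, had 240 footprint reads in the 2 libraries of 700 mOsm for 2 h and was not listed in unstressed cells. ENSMUST00000170693, with a coding length of 148 codons, had 1648 reads in the 2 unstressed libraries and was not listed at 700 mOsm for 2 h. No fold is given for either, since an unlisted transcript lay below the listing minimum.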

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

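All tests in this part, of differences between stressed groups and of explanations, were chosen after the results they weigh had been seen.

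Coding sequences of over 1600 codons stood at a median log2 footprint change of 1.67 after 15 min at 700 mOsm and at -0.65 after 2 h, a difference of 2.32 that was on opposite sides of 0 in both libraries of each time and was not tested. Few reads do not account for it, since the median after 15 min was 2.09 among transcripts with at least 100 expected reads, and the scaling does not either, since it was 1.16 on the values as deposited. RNA fragments without ribosomes, if taken up alike from all RNA, would leave footprint values in 1 proportion to RNA whatever the length. The median log2 ratio of footprint to RNA after 15 min was instead 2.76 higher over 1600 codons than at 400 to 800 codons. That ratio cannot exclude fragments that entered the pooled gradient fractions more readily from longer RNA. Ribosomes still travelling along long coding sequences after initiation had slowed stay possible but undecided. Within the class over 1600 codons Spearman's rho of change with coding length was 0.42 after 15 min and 0.27 after 2 h (373 transcripts), short of the 0.5 set for it. The rho of 0.73 above 800 codons restates in part the difference between the classes. In finer steps after 15 min the medians were -0.45 at 800 to 1200 codons, 0.73 at 1200 to 1600, 1.47 at 1600 to 2400, 1.98 at 2400 to 3600 and 2.48 above (29 transcripts). After 2 h they were -1.18, -1.0, -0.83, -0.61 and 0.19. Ribosomes that had halted within long coding sequences may give the same trend, and positions along the coding sequence were not analysed here.

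RNA differed between the libraries labelled 2 h of recovery after 15 min of stress and those labelled 15 min of recovery after 2 h of stress in 5065 of 9275 transcripts by limma's test of the difference. The first lay nearer to the RNA of 700 mOsm for 2 h (SD of log2 differences 0.354 against 0.596 for the second), and the second nearer to 15 min of recovery after the short stress (0.187 against 0.307), distances that involve no unstressed library. Of all groups, however, the first was nearest to 600 mOsm for 2 h (0.199). It also lay nearer to the unstressed cells (0.276) than to 700 mOsm for 2 h. Exchanged labels of these 2 RNA groups are a candidate explanation. The names of their RNA files read the other way round from the labels. Exchanging the groups raised Pearson's r of RNA and footprint changes to 0.58 and 0.45, the lower being within the range of the other conditions. Exchanged labels of the 2 footprint groups would raise r alike and cannot be told apart by it; the labelled RNA groups' distances to 700 mOsm for 2 h differed by -0.24, but which of them should lie nearer is not known. A biological difference between the 2 recoveries stays open, and untested.

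At 2 h of recovery from 2 h at 700 mOsm, 1300 transcripts with no read in the unstressed RNA libraries were listed in both RNA libraries, out of 3229 chosen for having no read in the controls. In the other conditions 24 to 217 such transcripts were listed in both. More reads do not account for it: thinned to 6851958 reads each, these libraries listed at least 14215 transcripts and the others at most 12931, a gap of 1284. Over the 3229 transcripts as a set, the reads did not fall evenly by length. Both libraries listed fewer of them than evenly spread reads would give, by 34.6% and 27.6%. At least 10 reads fell on 281 and 310 of them, and up to 134 and 173 on 1. A background that was even only in part stays open. The other RNA libraries fell short of even reads by more, 37.0% to 65.6%, so the shortfall cannot decide for or against an even background. RNA of other cells and newly made RNA also stay open, since without gene names neither was tested, and the levels were low, with a median of 0.056 and 0.054 FPKM.

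RNA also differed between 15 min and 2 h at 700 mOsm, in 4729 transcripts by limma's test of the difference, of which 2075 were higher and 2654 lower at 2 h (1318 higher without replicate 2 of 700 mOsm for 2 h).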

How the results depend on the processing

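Limma-voom on recovered reads, the sets of well-read transcripts and the fit without the 2 RNA groups in doubt were added after seeing the data, and the planned tests of footprints and translational efficiency became an alternative then; the other alternatives were fixed before. A pseudocount of 0.25 and the values as deposited kept total counts (higher plus lower) within 1.5 times the reported ones, though not each split, except for footprints at 15 min of recovery from the short stress, where the pseudocount gave 178 transcripts (the cause was not tested). Without the filter on low values that comparison gave 216 for footprints, 220 for translational efficiency and 1067 for RNA, from more transcripts examined. The RNA fit without the 2 groups in doubt moved no total by over 1.5 times. At 700 mOsm, among transcripts with at least 100 expected reads, 1608 were past 2-fold in footprints after 15 min and 1573 after 2 h. With the set drawn from the unstressed libraries these were 1828 and 1827. The counts were lower because 2784 and 3068 transcripts were examined. As shares they were 57.8% and 56.5%, and 59.6% at both times with the second set, against 65.7% and 64.0% of all 8849 transcripts.

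Equal weights, in place of a weight of 0.32 for the unstressed group, gave 936 RNA calls at 500 mOsm, 2285 at 600 mOsm, and in recovery 1415 and 2902 after the short stress (15 min, 2 h as labelled) and 2847 and 3090 after the long stress. Voom on recovered reads gave 1634, 3162, 2073, 3575, 2443 and 3982 in the same order; the cause was not tested. Fitting the compared groups only gave 322, 502 and 877 for the first 3 recovery groups, with fewer libraries behind the spread. Leaving out each library gave RNA counts of 149 to 263 at 500 mOsm, 350 to 916 at 600 mOsm, 202 to 534 and 273 to 1091 for 15 min and 2 h of recovery from the short stress, and 257 to 1146 and 610 to 1908 from the long stress; the lone library left in a group was assumed to vary like the others. Total footprint and translational-efficiency counts stayed within 1.5 times in all such cases. Leaving out a footprint library is no check between samples, since the 2 of a condition were counted as 1.

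Replicate numbers were shared across groups, and same-numbered RNA libraries did not deviate in 1 common direction. The correlation of their deviations over 36 pairs of groups had a median of 0.007 and ran from -0.307 to 0.308. For the unstressed libraries it was 0.308 with 500 mOsm and -0.307 with 15 min of recovery from the short stress. Variation shared by some groups, whatever the replicate number, is therefore not excluded. With the replicate number as a block, RNA counts were 348 at 500 mOsm, 1313 at 600 mOsm, 4781 and 4732 at 700 mOsm for 15 min and 2 h, 678 and 1469 after the short stress and 1329 and 2264 after the long stress, no total moved by over 1.5 times. The reported footprint and translational-efficiency counts come from no test, so a block, equal weights and fits on the compared groups do not apply to them. The planned test of gene lists with an estimated correlation was not run, since no transcript could be given a gene name.

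Counting each deposited footprint library as a replicate, limma called 5551 transcripts at 500 mOsm, 6691 at 600 mOsm, 2465 and 2597 in recovery from the short stress, 4338 and 5495 in recovery from the long stress, and 5480 between the 2 recoveries of 2 h. For translational efficiency it called 3927, 5666, 851, 1954, 3481 and 3341. With the replicate number as a block (1 term per assay) the footprint calls were 5509, 6683, 2466, 2594, 4287, 5429 and 5453 in the same order, and those of translational efficiency 4034, 5721, 877, 2134, 3467 and 3455. These tests take for the spread of samples that of 2 libraries which differed by little more than sampling noise. Whether the 2 came from separate cultures is not known here. Exchanging the 2 RNA groups changed translational efficiency to 27 transcripts at 2 h of recovery from the short stress and 369 at 15 min of recovery from the long stress, by construction.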

Other observations

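At 2 h of recovery from 2 h at 700 mOsm, of the 747 transcripts with fallen RNA 135 had at least 2-fold lower footprint values and 1 at least 2-fold higher, and of the 6536 with no RNA call 468 had lower and 35 higher values. Of 50 transcripts without an RNA read in unstressed cells that were in the footprint lists, 13 had footprints in both libraries at this time and 1 in unstressed cells.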
